A study of Homo sapiens with 18 samples.

How the data were processed

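The samples were 18 libraries of newly made RNA from MDA-MB-453 cells, an established luminal breast cancer line. Per the labels' protocols, cells received DMSO or the BET degrader JQ1-VHL for 3 hours, and 0.1 mM 4-thiouridine was in the medium for the last 60 minutes. The sample titles name the drug dBET, while the series description names it JQ1-VHL, and the latter name is used here. Cytoplasmic and nuclear RNA were separated with 1 mg/ml digitonin, and total RNA was kept as a further fraction. The RNA was treated with iodoacetamide, so that incorporated 4-thiouridine reads as a T-to-C change, and polyadenylated RNA was sequenced as 150 bp read pairs. Per the labels' protocols, ERCC RNA was added after extraction in proportion to the mass of RNA, and Drosophila cells were added by cell count before permeabilisation. An ERCC scale set by RNA mass measures T-to-C reads per mass of recovered RNA and not per cell.

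The submitters' processing notes name bcl2fastq, Trimmomatic 0.39, HISAT2, HTSeq and DESeq2, and the builds GRCh37/hg19 and dm3, without their roles or order. The calling of T-to-C reads, the counting rule, the strand counted and any filter on the table are not stated. The unit recorded for the deposited table is signal: T-to-C read counts divided by 1 factor per library, per its name an ERCC factor. All values of a library were whole multiples of its smallest value, within 0.01 of a read, so whole reads were recovered. The libraries held 1.58 to 6.77 M such reads (M stands for 1e06), and 1 read was worth 0.470 to 2.75 units. PCR reads without molecular identifiers are not independent molecules, so floors set at 3 counts in each library of a group cover counting error only.

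The table held 98665 intervals named by a gene ID and a number, although the comparisons were designed for genes. For 4912 of 12755 gene IDs the highest number equalled the number of gaps between the gene's merged exons in GENCODE 29. Of 1117 protein-coding genes of 1 exon block, 11 were in the table, against 10862 of 18834 with more blocks. Within genes, DMSO nuclear reads correlated with gap length when intervals were numbered along the genome. The median Spearman correlation within a gene was 0.393 over 1342 plus-strand genes and 0.400 over 1081 minus-strand genes, against 0.0352 and 0.0462 in the opposite order. Neighbouring intervals often held nearly equal reads: of 1258 pairs with at least 1000 reads, 20.7% differed by under 2% in the cytoplasm and 8.90% in the nucleus. Reads counted in more than 1 interval would give such pairs, but whether spliced reads were counted was not settled. A gene's intervals were summed, so a fragment counted in several intervals adds to the sum each time. No interval existed for HEXIM1, MALAT1, NEAT1, MT-CO1, JUN or DDX39B, and no ERCC, Drosophila or mitochondrially encoded lines were present. Every per-sample column was used.

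Choices made before the data were examined were the test, the filter, the lists, the naming rule and most alternatives. Genes with a mean of at least 10 over the 18 libraries were tested, which kept 10191 genes and 99.8% of the summed value. The test was limma with trend and robust eBayes on log2(value + 1), with 1 mean for each of the 6 groups of 3 libraries, two-sided, adjusted by Benjamini-Hochberg at 0.05. The 6 comparisons were JQ1-VHL against DMSO in each fraction, the nuclear minus the cytoplasmic effect, and nuclear against cytoplasmic RNA under each treatment. "Rescaled" values were divided by a median-of-ratios factor over the tested genes. The factor sets each library against the mean of all 18 libraries, so changes are only roughly relative to the typical gene of a fraction. P-values measure only the spread between these samples, since the labels do not say that replicates were separate cultures. On the ERCC scale the limma fit treated the variance of a gene as known, and not as estimated from a few libraries. In some groups the genes of a library shared most of their deviation, so they are not independent evidence on that variance. Calls on the ERCC scale therefore carry more certainty than so few libraries can give. An exact two-sided permutation test of 3 libraries against 3 cannot give a p under 0.1. The pairing comes from the labels, which give each library a batch number equal to its replicate number. In the check of that pairing, the correlations of the gene deviations of same-numbered DMSO and JQ1-VHL libraries were 0.22, 0.08 and 0.16 in total RNA, 0.27, -0.14 and 0.29 in nuclear RNA, and 0.06, -0.05 and 0.02 in cytoplasmic RNA, so the values did not show it in every pair. The batch number entered as a block in an alternative.

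The 22 gene lists included P-TEFb and the super elongation complex, immediate early mRNAs, MYC targets, ribosomal proteins, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, mRNA export factors, nuclear speckle and SR proteins, nuclear RNA decay, RNA polymerase II and general factors, nuclear noncoding RNAs, snoRNA hosts, detained-intron genes, endoplasmic reticulum and secretory mRNAs, luminal genes, E2F and S-phase genes, G2/M genes, histones, heat shock, cholesterol synthesis, and markers of other lineages. Lists were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry, which tests whether a list moves one way. P-values were adjusted over the lists of a comparison.

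Named genes were the 8 highest and 8 lowest log2 changes among calls with the same sign in all 3 same-numbered pairs and a group mean of at least 50. Clone names and pseudogenes were left out. A further set was fixed beforehand, among them BRD2, BRD3, MYC, HEXIM1, SERPINI1, CDK9, GATA3, FOXA1, ERBB2, NXF1, ALYREF, DDX39B, THOC1, SON, SRRM2, MALAT1, NEAT1, ACTB, GAPDH, MT-CO1, MCL1, JUN and FOS. SERPINI1 was under the filter. Up to 4 members of each list, those of highest and lowest moderated t, were available as examples.

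Alternatives were other pseudocounts and filters, rescaling, a fit of the compared groups alone, the block, eBayes without trend or robust, edgeR and DESeq2 on whole reads, edgeR with TMM, and leaving out each library in turn. Chosen after seeing the data were tests per interval, the highest interval per gene, leaving out DMSO cytoplasmic replicate 3 and JQ1-VHL nuclear replicate 3 together, and rescaling combined with leaving out libraries. Applying the naming rule to rescaled values, and comparing intervals by length, were also chosen then.

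The fit was tested on simulated data with 50 genes planted at each of -2, -1, 1 and 2 on the log2 scale. On the ERCC scale limma called 0 of the planted genes at any of these sizes, although the estimates were close to the planted values (median -1.97 for -2 in total RNA). After rescaling it called 92% at -2 and 100% at 2 in nuclear RNA with 0 false calls, and 48% at -1 and 58% at 1. In cytoplasmic RNA 48 calls were false, 23.0% of the calls made. Of these, 24 were in genes with under 10 reads in that fraction.

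Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.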

Results

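The comparisons asked how a 3-hour treatment with the BET degrader JQ1-VHL changed newly made polyadenylated RNA in the whole cell, the nucleus and the cytoplasm of MDA-MB-453 cells. Values are ERCC-scaled T-to-C read counts, called units here, summed over the intervals of a gene. Group values are mean ± SD of 3 libraries, and log2 changes are estimate ± SE with adjusted p from limma unless another test is named.

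The summed new RNA of the nucleus was 1.44 ± 0.647 M units per library under JQ1-VHL and 3.25 ± 1.40 M under DMSO, a ratio of 0.444. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. The ratio was 0.315, 0.798 and 0.323 in the same-numbered pairs. Total RNA held 5.68 ± 0.365 M units under JQ1-VHL and 5.64 ± 4.50 M under DMSO (ratio 1.01, exact permutation p = 1), with pair ratios of 0.564, 1.95 and 1.67. Without DMSO total replicate 1 that ratio was 1.87. Cytoplasmic RNA held 10.0 ± 2.29 M units under JQ1-VHL and 9.69 ± 8.48 M under DMSO (ratio 1.04, exact permutation p = 1), with pair ratios of 1.21, 6.72 and 0.407. Without DMSO cytoplasmic replicate 3 that ratio was 1.93. The DMSO cytoplasmic sums spread 10.4-fold between replicates, so a change of the cytoplasmic sum of the size seen in the nucleus was not detectable.

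**Figure D1:**
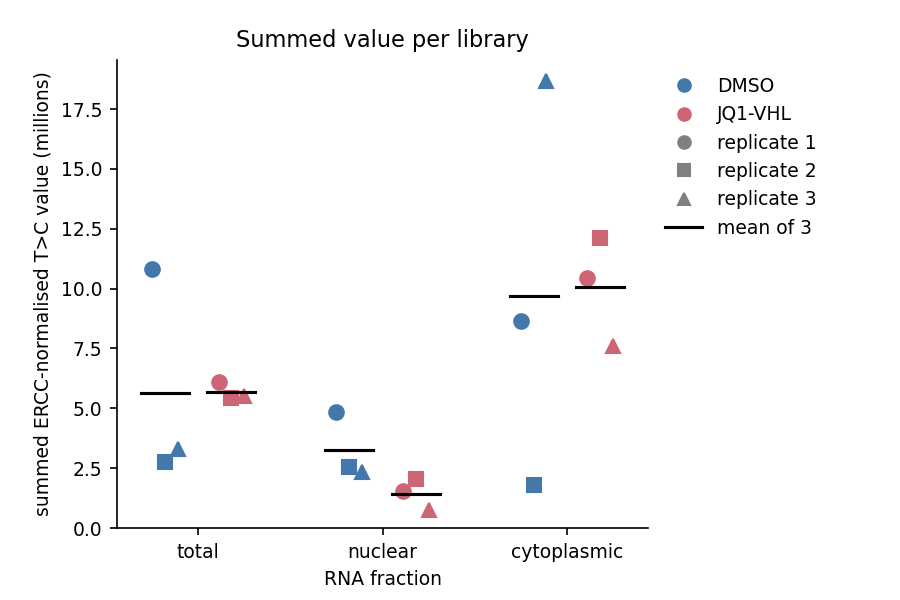
Summed T-to-C value per library in Ms of ERCC-scaled units, for DMSO and JQ1-VHL in total, nuclear and cytoplasmic RNA; points are libraries and bars are means of 3. The nuclear means are 3.25 M under DMSO and 1.44 M under JQ1-VHL, and the DMSO cytoplasmic libraries spread from 1.80 to 18.7 M.

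The median of genes measured the change without the weight of abundant mRNAs. The median log2 change over the 10191 tested genes was -2.23, -0.72 and -2.42 in the nuclear pairs, with a mean of -1.79 ± 0.93 (SD of 3 pairs). It was -0.47 ± 0.90 in total RNA and -0.01 ± 2.05 in cytoplasmic RNA, both within the spread of the pairs. Recovered T-to-C reads were fewer under JQ1-VHL in the nucleus, at 2.54 ± 0.838 M per library against 5.14 ± 0.713 M under DMSO. Sequencing depth is not known, so depth and the amount of new RNA cannot be told apart in this count. JQ1-VHL nuclear replicate 3 held the fewest, with 1.58 M reads and 30.5% of intervals at 0. Rescaling moved the median of the fitted changes from -0.49 to -0.01 in total RNA, from -1.82 to 0.16 in nuclear RNA and from -0.02 to 0.30 in cytoplasmic RNA. The typical gene of a fraction was therefore not always at 0 after rescaling. Rescaled counts and list medians carry these offsets, also where fractions are compared. A gene whose ERCC-scaled value fell by clearly less than the typical gene is higher after rescaling.

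In nuclear RNA JQ1-VHL lowered new transcripts of SPDEF, FOXA1, GATA3 and MYC. SPDEF, an ETS factor of secretory epithelium (GRCh38 chromosome 6, 34537802 to 34556333, GENCODE 29), had 33.7 ± 25 units under JQ1-VHL and 1946 ± 985 under DMSO. Its log2 change was -6.08 ± 0.88 (adjusted p = 3.7e-08), and -4.10 after rescaling. The pioneer factor FOXA1 changed by -5.05 ± 0.91 (adjusted p = 1.8e-05) and the luminal factor GATA3 by -2.88 ± 0.80 (adjusted p = 0.0051). The growth regulator MYC (GRCh38 chromosome 8, 127735434 to 127741434, GENCODE 29) had 4.97 ± 2.69 units under JQ1-VHL and 231 ± 44.3 under DMSO, a change of -5.37 ± 1.00 (adjusted p = 3.9e-05), and -3.39 after rescaling. The 8 lowest log2 changes included -6.64 ± 1.11 for the endothelin gene EDN2 (adjusted p = 4.3e-06) and -6.27 ± 1.11 for the growth factor binder IGFBP3 (adjusted p = 1.4e-05). The phosphodiesterase gene PDE4B changed by -5.85, the glutamate transporter gene SLC1A7 by -5.73 and the nucleotide receptor gene P2RY6 by -5.69. The long noncoding RNA SILC1 (-6.12) and FAM98C (-5.64), which overlaps RASGRP4, completed the 8 lowest.

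Fewer genes rose in the nucleus, 18 in all. NFE2L3, which encodes a bZIP transcription factor, had 861 ± 669 units under JQ1-VHL and 83.3 ± 41.9 under DMSO (log2 change 2.95 ± 0.89, adjusted p = 0.0094). It overlaps HNRNPA2B1, and the strand counted is not stated, so the source of its reads is uncertain. The replication histone gene H3C12 had 841 ± 581 units against 106 ± 71.2 (2.83 ± 0.88, adjusted p = 0.011) and overlaps the histone gene HIST1H2AM. The germ-cell bridge gene TEX14, which overlaps AC011195.2, rose from 5.40 ± 4.05 to 88.3 ± 46.9 units (3.84 ± 1.11, adjusted p = 0.0069), and NUP210L, a testis paralogue of a nuclear pore gene, rose by 3.59. GRAPL, an adaptor gene whose near copy GRAP leaves the source of its reads uncertain, rose by 4.76 ± 1.16 (adjusted p = 0.0018). The kinase gene NIM1K rose by 3.00, TRIM59, which overlaps SMC4, by 4.39, and KANK3, which overlaps RPS28, by 3.23.

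Among genes of the BET family, which the drug targets at the protein level, BRD2 changed by -2.21 ± 0.81 (adjusted p = 0.026) and BRD3 by -2.50 ± 0.94 (adjusted p = 0.030) in the nucleus. After rescaling these were -0.24 and -0.52, and neither was called. The kinase gene CDK9 (-2.47, adjusted p = 0.033) and the export adaptor gene ALYREF (-2.06, adjusted p = 0.048) also fell only on the ERCC scale. The export receptor gene NXF1 (-0.47), the speckle genes SON (-0.87) and SRRM2 (-0.62), the receptor gene ERBB2 (-0.68), the survival gene MCL1 (-1.01), the actin gene ACTB (-0.22) and the glycolytic gene GAPDH (-0.34) were not called. All 7 turned higher after rescaling, at 1.51, 1.11, 1.36, 1.30, 0.97, 1.75 and 1.64. ACTB had 8603 ± 3859 units under JQ1-VHL and 9606 ± 3510 under DMSO. BRD2, BRD3, ALYREF, SON, SRRM2 and ERBB2 overlap other protein-coding genes. The immediate early gene FOS (1.34, adjusted p = 0.20) was called only after rescaling (3.31, adjusted p = 0.015).

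Across all genes, nuclear RNA had 18 genes higher and 3435 lower, and 5014 genes had an unadjusted p under 0.05. After rescaling 2180 were higher and 819 lower, and edgeR with TMM gave 1513 higher and 1617 lower, so the balance of directions rests on the scale. The count on the ERCC scale was 308 without DMSO nuclear replicate 1, 2236 without DMSO nuclear replicate 2 and 239 without JQ1-VHL nuclear replicate 3. Of 24 named calls, 17 were kept without DMSO replicate 1 (NIM1K, BRD2, BRD3, CDK9, GATA3 and ALYREF were among those lost), 18 without DMSO replicate 2 (KANK3, NIM1K, BRD2, BRD3, CDK9 and ALYREF) and 20 without DMSO replicate 3 (NUP210L, KANK3, NIM1K and H3C12). Without JQ1-VHL replicates 1, 2 and 3, the calls kept were 22 (lost were KANK3 and NIM1K), 20 (KANK3, NIM1K, NFE2L3 and H3C12) and 17 (KANK3, BRD2, BRD3, CDK9, GATA3 and ALYREF among those lost). edgeR on the ERCC scale kept 19 (lost were KANK3, BRD2, BRD3, CDK9 and ALYREF), and DESeq2 kept 19 (GRAPL, KANK3, BRD2, BRD3 and ALYREF). The rescaled count was 1892 without DMSO nuclear replicate 1.

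**Figure D2:**
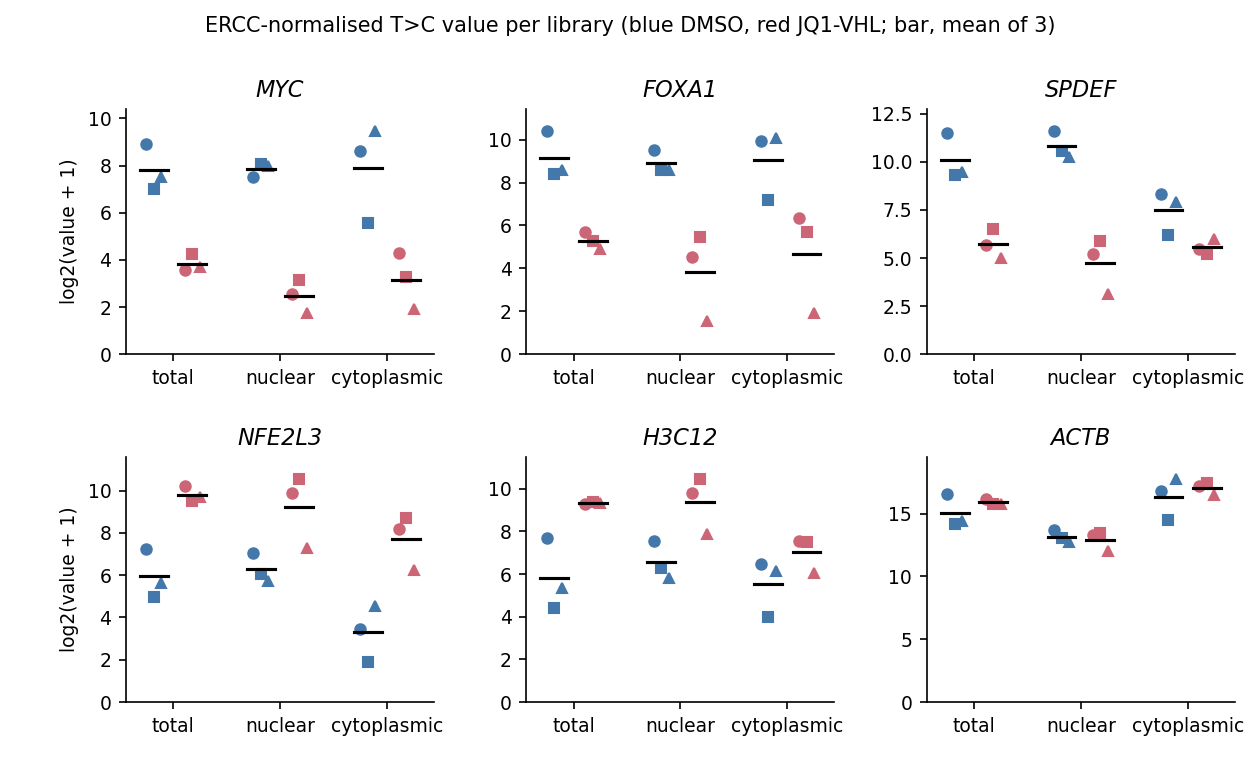
T-to-C value per library, as log2(value + 1) in ERCC-scaled units, for MYC, FOXA1, SPDEF, NFE2L3, H3C12 and ACTB in 3 fractions under DMSO and JQ1-VHL; points are libraries, with 1 marker shape per replicate number, and bars are means of 3. In nuclear RNA MYC, FOXA1 and SPDEF change by -5.37, -5.05 and -6.08, NFE2L3 and H3C12 by 2.95 and 2.83, and ACTB by -0.22, which is 1.75 after rescaling.

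Of 13 histone genes, 2 were higher in the nucleus over all genes and 2 adjusted over the list alone, H3C12 and H2BC5 (2.32, adjusted p = 0.026). After rescaling 11 were higher, also adjusted over the list alone. The list's median was 1.28, and 3.26 after rescaling, and on the ERCC scale its pair medians were 1.12, 2.51 and -0.10. camera gave an adjusted p of 2.33e-18. With an estimated correlation camera gave an adjusted p of 0.234 on the ERCC scale and 0.0277 after rescaling. The RNA was polyadenylated, and the table held only 11 of 1117 protein-coding genes of 1 exon block. Which transcripts of the histone genes gave these reads, in any fraction, is therefore not known. A rise of histone mRNA was not separated from other transcripts of these genes. Ribosomal protein mRNAs had a median of -0.73 against -1.82 for all genes, and of the 68, 0 were higher and 2 lower (RPL7 and RPSA), with 0 adjusted over the list alone. After rescaling 43 were higher and 0 lower (48 adjusted over the list alone), led by RPS20 at 3.54. camera placed them above other genes (adjusted p = 2.36e-08, adjusted p = 0.96 with an estimated correlation), so that call was lost with the estimate. Cholesterol synthesis genes behaved alike, with 2 of 20 lower, 0 adjusted over the list alone and 12 higher after rescaling (camera adjusted p = 0.0179, adjusted p = 0.96 with an estimated correlation). DHCR7 (-2.19) was among those lower, while IDI1 was 2.32 after rescaling.

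The lists closest to the series' subject, nuclear speckles and mRNA export, had nuclear medians of -1.41 and -1.36, against -1.82 for all genes. Of 39 speckle and SR protein genes, 7 were lower (2 adjusted over the list alone), with CLK4, a kinase of SR proteins, at -3.54 (adjusted p = 0.0054) and the splicing factor gene SRSF6 at -2.70. After rescaling 16 were higher and 2 lower, with SRPK1 at 1.45 (-0.53 on the ERCC scale). camera passed only after rescaling (adjusted p = 0.00321, adjusted p = 0.0304 with an estimated correlation). Of 31 export genes, 6 were lower (3 adjusted over the list alone), among them the TREX genes THOC7 (-3.55) and THOC3 (-3.40). After rescaling 11 were higher and 0 lower, and camera gave 0.0249, with adjusted p = 0.231 with an estimated correlation. Of 15 heat shock genes, 4 were lower (3 adjusted over the list alone), including AHSA1 (-2.70), and 9 were higher and 0 lower after rescaling, with camera at 0.00332 and adjusted p = 0.0304 with an estimated correlation.

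Of 17 P-TEFb and super elongation complex genes, 11 were lower in the nucleus (12 adjusted over the list alone), including NELFCD (-4.37, adjusted p = 0.00057) and NELFE (-4.03), subunits of the pausing factor NELF. After rescaling 5 were lower and 1 higher, and camera passed only then (adjusted p = 0.0344, adjusted p = 0.231 with an estimated correlation). Of 22 luminal genes, 12 were lower (13 adjusted over the list alone), including TFAP2B (-5.44, adjusted p = 1.9e-06), with 9 lower and 8 higher after rescaling, among the latter ALCAM at 1.64 (-0.34 on the ERCC scale). camera did not pass for this list (adjusted p = 0.0838, and 0.136 after rescaling). Of 27 immediate early mRNAs, 14 were lower (15 adjusted over the list alone), including ZFP36L1 (-4.46), with 7 lower and 7 higher after rescaling, where EGR1 reached 3.32. Of 29 MYC targets, 11 were lower (11 adjusted over the list alone), including SRM (-4.03) and DKC1 (-3.38), with 12 higher and 3 lower after rescaling.

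In the nucleus no further list had a gene higher on the ERCC scale. The genes lower, over all genes and then adjusted over the list alone, were 12 and 11 of 41 endoplasmic reticulum and secretory genes (PIP, -4.93), 12 and 14 of 29 oxidative phosphorylation genes (NDUFS8, -4.34), 9 and 12 of 20 RNA decay genes (PAPOLG, -4.22), and 11 and 11 of 31 RNA polymerase II genes (POLR2K, -3.46). They were 13 and 16 of 30 E2F genes (E2F2, -3.30), 4 and 0 of 25 G2/M genes (CENPF, -2.56), 3 and 3 of 17 snoRNA hosts (SNHG11, -3.32), 6 and 3 of 20 detained-intron genes (RBM5, -2.79), and 1 and 0 of 7 noncoding RNAs (PVT1, -2.24). G2/M genes passed camera after rescaling (adjusted p = 0.0178, adjusted p = 0.706 with an estimated correlation). Of the markers of other lineages, 2 were tested, COL1A1 (-1.49, adjusted p = 0.13) and ALB (-0.13, adjusted p = 0.91). On the ERCC scale 0 were called by limma. After rescaling their median stood at 1.17 ± 0.51 in nuclear, 1.55 ± 0.29 in total and 1.78 ± 1.25 in cytoplasmic RNA (SD of 3 pairs). Ribosomal proteins stood at 1.22, 0.94 and 0.90 in the same order. The mitochondrially encoded list had 0 genes in the table.

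**Figure D3:**
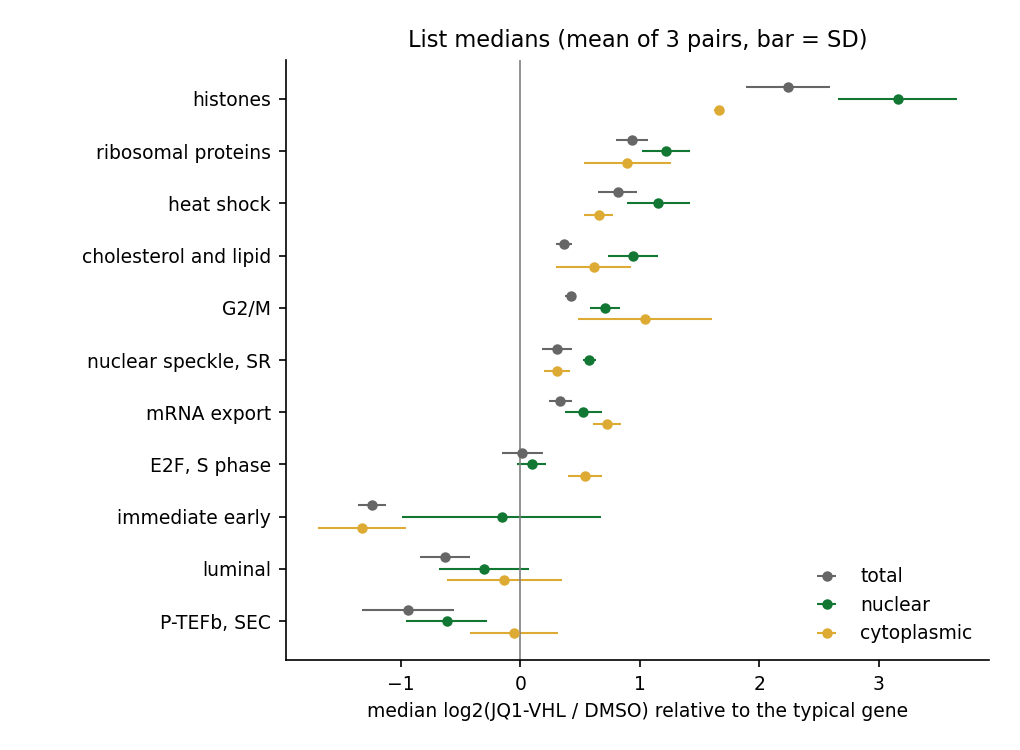
Median rescaled log2 change of 11 gene lists, JQ1-VHL against DMSO, in total, nuclear and cytoplasmic RNA. Points are means of 3 same-numbered pairs and bars their SD. The reference line is not the median of all genes in each fraction. Histones sit at 2.24, 3.16 and 1.66 and ribosomal proteins at 0.94, 1.22 and 0.90 in total, nuclear and cytoplasmic RNA; on the ERCC scale the ribosomal proteins sit at -0.76 in the nucleus.

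In total RNA some of the same regulators fell. MYC had 13.7 ± 3.82 units under JQ1-VHL and 262 ± 188 under DMSO, a change of -3.96 ± 1.00 (adjusted p = 0.011). FOXA1 changed by -3.84 ± 0.91 (adjusted p = 0.0074), and IGFBP3 (GRCh38 chromosome 7, 45912245 to 45921874, GENCODE 29) fell from 204 ± 171 to 2.01 ± 3.47 units (-6.43 ± 1.11, adjusted p = 7.3e-05). The mitochondrial ribosome gene MRPL36 had 0 reads in all 3 JQ1-VHL libraries and 73.3 ± 78.2 units under DMSO, at least 19.4-fold lower, and at least 7.53-fold lower without DMSO replicate 1. The other lowest were C16orf87 (-5.54), the Pol III factor gene BRF2, which overlaps ADGRA2 (-5.50), PHF23 (-5.25), P2RY6 (-5.17), ANKRD50 (-5.10) and PDE4B (-5.03). GATA3 (-1.98, adjusted p = 0.15), BRD2 (-1.77, adjusted p = 0.22), BRD3 (-1.48, adjusted p = 0.46) and CDK9 (-2.37, adjusted p = 0.15) were not called on the ERCC scale. After rescaling GATA3 (-1.50, adjusted p = 5.1e-05), BRD2 (-1.29, adjusted p = 0.015) and CDK9 (-1.89, adjusted p = 0.013) were called lower, and BRD3 was not called (adjusted p = 0.13).

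The 8 named genes higher in total RNA had means of 0 to 9.01 units under DMSO. GRAPL had 64.1 ± 5.53 units under JQ1-VHL and 0 reads in all 3 DMSO libraries, at least 18.8-fold higher. NIM1K rose from 9.01 ± 6.76 to 188 ± 38.0 units (4.62 ± 1.07, adjusted p = 0.0065), and HCLS1, a cortactin-like gene of blood cells, from 2.15 ± 2.29 to 75.1 ± 25 (4.86, adjusted p = 0.0074). TRIM59, which overlaps SMC4 (4.86), the meiotic gene MCMDC2 (4.43), the antisense RNAs IDI2-AS1 (4.37) and GUCY2C-AS1 (4.25), which overlap IDI2 with IDI1 and GUCY2C, and the channel gene TMC2 (4.16) followed. Of 13 histone genes 2 were higher (6 adjusted over the list alone), H3C12 (3.52, adjusted p = 0.011) and H2BC5 (2.88, adjusted p = 0.032), and 10 after rescaling. Their camera adjusted p was 4.6e-10, with adjusted p = 0.987 with an estimated correlation. Of 27 immediate early mRNAs 5 were lower (9 adjusted over the list alone), including the phosphatase gene DUSP5 (-4.30, adjusted p = 0.0074), with a camera adjusted p of 0.0244 and adjusted p = 0.996 with an estimated correlation. Ribosomal protein genes had a median of 0.45 with 0 called by limma in either direction, over all genes or adjusted over the list alone, and 39 were higher and 3 lower after rescaling. camera placed them above other genes (adjusted p = 1.14e-05, adjusted p = 0.996 with an estimated correlation).

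Over all genes total RNA had 25 higher and 284 lower (1714 at an unadjusted p under 0.05), and 1741 higher and 1672 lower after rescaling. With the batch number as a block the count rose from 309 to 583. It was 27 (14 higher and 13 lower) without DMSO total replicate 1, 188 without DMSO replicate 2, 113 without DMSO replicate 3, 105 without JQ1-VHL replicate 2 and 18 without JQ1-VHL replicate 3. Of 18 named calls, 11 were kept without DMSO replicate 1 (lost were HCLS1, TRIM59, IDI2-AS1, TMC2, P2RY6, MYC and FOXA1) and 8 without JQ1-VHL replicate 3 (TRIM59, NIM1K, MCMDC2, IDI2-AS1, GUCY2C-AS1, TMC2, PHF23, P2RY6, MYC and FOXA1). Without DMSO replicate 2 the calls of NIM1K, IDI2-AS1 and TMC2 were lost, without DMSO replicate 3 those of MCMDC2 and GUCY2C-AS1, without JQ1-VHL replicate 1 those of GUCY2C-AS1 and TMC2, and without JQ1-VHL replicate 2 that of TMC2. A pseudocount of 0.1 kept 11, edgeR on the ERCC scale lost TMC2 and DESeq2 lost P2RY6. The rescaled count of 3413 was 2115 without DMSO replicate 1, 2257 without DMSO replicate 2, 2292 without JQ1-VHL replicate 2, with more lower than higher, and 1936 without JQ1-VHL replicate 3.

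In cytoplasmic RNA the lowest log2 change was that of IRS1. This insulin receptor adaptor gene had 2.79 ± 4.84 units under JQ1-VHL and 169 ± 120 under DMSO (-5.87 ± 1.09, adjusted p = 0.0002). The MAP kinase phosphatase gene DUSP4 changed by -5.66 ± 1.07 (adjusted p = 0.0002), the BMP mediator gene SMAD1 by -5.54 and the pseudokinase gene TRIB2 by -5.48. DCK, which overlaps MOB1B (-5.64), ZSCAN12 (-5.46) and DR1 (-5.46) were also among the lowest. Their changes were smaller in pair 2, at -2.91, -2.12 and -0.59. DR1 had 14.3 ± 24.8 units under JQ1-VHL and 179 ± 98.9 under DMSO. MYC had 10.1 ± 8.13 units against 377 ± 325 (-4.71 ± 1.00, adjusted p = 0.00091), and FOXA1, which overlaps TTC6, changed by -4.40 ± 0.91 (adjusted p = 0.00054). BRD3 was lower (-3.04 ± 0.94, adjusted p = 0.037), while BRD2 (-1.56, adjusted p = 0.40) was called only after rescaling (-1.24, adjusted p = 0.016). Higher were TEX14, with 86.2 ± 40.2 units against 0.368 ± 0.638 (5.96 ± 1.11, adjusted p = 0.0002), NUP210L (5.49) and NFE2L3, with 259 ± 171 units against 11.6 ± 9.74 (4.41 ± 0.89, adjusted p = 0.00046). GUCY2C-AS1 (4.37), MEIOB, which overlaps FAHD1 (4.26), PLA2G10 (3.90), TSPAN31, which overlaps CDK4 (3.75), and MAP2 (3.70) were the rest of the 8 highest.

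Of 27 immediate early mRNAs in the cytoplasm, 6 were lower and 1 higher (11 and 2 adjusted over the list alone). ZFP36L1, which encodes an mRNA decay factor, changed by -4.64 (adjusted p = 0.0002), while EGR1, a growth-response factor gene, was higher (3.57, adjusted p = 0.0084). The list's pair medians were -1.57, 0.46 and -3.83. Its camera adjusted p, relative to other genes, was 9.2e-06, with adjusted p = 0.991 with an estimated correlation. Of 22 luminal genes 2 were lower (4 adjusted over the list alone), among them the unfolded-protein-response factor gene XBP1 (-3.43, adjusted p = 0.003). The methylphosphate capping gene MEPCE (-3.06, adjusted p = 0.047) was the 1 of 17 P-TEFb genes called (2 adjusted over the list alone). The export cofactor gene NXT1 (-3.70, adjusted p = 0.034) was the 1 of 31 export genes called (1 adjusted over the list alone). Histones had 0 calls by limma on the ERCC scale, over all genes or adjusted over the list alone, with a median of 1.42, and 9 were higher after rescaling (10 adjusted over the list alone). Camera passed for histones (0.00156), ribosomal proteins (0.00156), G2/M genes (0.0132) and nuclear noncoding RNAs (0.0481), each with adjusted p = 0.991 with an estimated correlation.

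Cytoplasmic RNA had 23 genes higher and 374 lower (1346 at an unadjusted p under 0.05), and 2511 higher and 1461 lower after rescaling. These calls leaned on the spread pooled over all 18 libraries: with only the cytoplasmic libraries in the fit limma called 0 genes, so all 19 named calls were lost. edgeR on the ERCC scale called 15 of them (lost were MEIOB, PLA2G10, TSPAN31 and MAP2), DESeq2 17 (lost were PLA2G10 and MAP2) and edgeR with TMM 18 (lost was PLA2G10). With the block the count rose from 397 to 619. It was 87 without DMSO cytoplasmic replicate 1, 1287 without DMSO replicate 2, 74 without DMSO replicate 3 and 116 without JQ1-VHL replicate 3. The named calls lost were MEIOB and BRD3 without DMSO replicate 1, PLA2G10 without DMSO replicate 2, and GUCY2C-AS1, PLA2G10, TSPAN31, MAP2 and BRD3 without DMSO replicate 3. They were PLA2G10, MAP2 and BRD3 without JQ1-VHL replicate 1, TSPAN31 and BRD3 without JQ1-VHL replicate 2, and MAP2, BRD3 and FOXA1 without JQ1-VHL replicate 3.

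Fractions shared more calls than chance gives for sets of genes drawn independently. Total and nuclear RNA shared 270 genes lower where chance gives 95.7, and 14 higher, GRAPL and NIM1K among them, where chance gives 0.0442. Total and cytoplasmic RNA shared 103 lower (10.4 by chance) and 5 higher (0.0564 by chance). Nuclear and cytoplasmic RNA shared 301 lower, MYC and FOXA1 among them (126 by chance), and 4 higher, with NFE2L3 and TEX14 among them (0.0406 by chance). Across the 10191 genes, which are not independent replicates, the log2 changes had Spearman correlations of 0.855 between total and nuclear, 0.705 between total and cytoplasmic and 0.574 between nuclear and cytoplasmic RNA. Each fraction had its own DMSO libraries, but total RNA contains the RNA of both compartments, and 1 fit gave every comparison. Some excess over independent sets therefore follows from the design.

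Whether the drug acted differently in the 2 compartments was tested as the nuclear minus the cytoplasmic effect. The pausing factor gene NELFCD had 19.9 ± 15 units under JQ1-VHL and 354 ± 215 under DMSO in the nucleus, but 72.1 ± 26.8 and 54.0 ± 35 in the cytoplasm. MAB21L4 had 27.5 ± 21.5 and 804 ± 472 in the nucleus, against 46.6 ± 9.12 and 51.2 ± 32.1 in the cytoplasm. Their differences after rescaling were -3.37 ± 0.59 (adjusted p = 0.0052) and -3.71 ± 0.61 (adjusted p = 0.0033). The LIM-domain gene CRIP2 (-4.04), FAH (-3.71), ISG20 (-3.56), MCIDAS (-3.53), CNKSR1 (-3.44) and LAD1, which overlaps TNNT2 (-3.36), made up the rest of the 8 lowest. In the other direction, YWHAH, which encodes a 14-3-3 protein and overlaps Z82190.2, had 106 ± 67.0 and 160 ± 94.7 units in the nucleus but 37.8 ± 33.2 and 346 ± 344 in the cytoplasm (4.24 ± 0.73, adjusted p = 0.0044). MSL2 (4.64), PLEKHF2 (4.62), NUDT4 (4.46), ZKSCAN2 (4.39), SPTY2D1 (4.34), SNRK (4.24) and TOPORS (4.23) were the other highest, of which NUDT4, SPTY2D1, SNRK and TOPORS overlap other protein-coding genes.

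None of these passed on the ERCC scale, where limma called 0 genes (1564 at an unadjusted p under 0.05), edgeR 0, DESeq2 24 and limma with the block 8. The median difference was -1.64, -2.78 and -0.43 in the pairs (-1.62 ± 1.18). After rescaling 130 genes were higher and 168 lower, and edgeR with TMM gave 108 and 237. On the ERCC scale the count was 8 without DMSO cytoplasmic replicate 1, 2 without DMSO cytoplasmic replicate 2 and 106 without DMSO cytoplasmic replicate 3. The rescaled count of 298 was 115, 95 and 119 without DMSO nuclear replicates 1, 2 and 3, and 161 and 150 without JQ1-VHL nuclear replicates 1 and 2. It was 512 without DMSO cytoplasmic replicate 3 and 457 without JQ1-VHL cytoplasmic replicate 1, there with 239 higher and 218 lower. Of 13 histone genes 0 were called by limma on the ERCC scale and 3 after rescaling (9 adjusted over the list alone), with H3C12 at 2.99 (adjusted p = 0.0023). Of 27 immediate early mRNAs 0 were called on the ERCC scale and 4 after rescaling (9 adjusted over the list alone), with KLF6 at 3.35 (adjusted p = 0.00089). Both lists passed camera as higher in the nucleus (adjusted p = 8.97e-05 each), and both missed it with adjusted p = 0.997 with an estimated correlation.

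In DMSO, FTL and RPS12 were among the most cytoplasmic mRNAs. The ferritin mRNA FTL had 369 ± 32.4 units in the nucleus and 17478 ± 22413 in the cytoplasm (-4.58 ± 0.80, adjusted p = 1.4e-05). The ribosomal protein mRNA RPS12 (-4.76 ± 0.74, adjusted p = 7.0e-07), TPT1 (-4.44), RPS6 (-4.24), SH3BGRL (-4.50), AP3S1 (-4.31) and SEM1 (-4.21) were also cytoplasmic, as was ACTB (-3.19 ± 0.74, adjusted p = 0.00076). Nuclear were GPR108, which overlaps C3, with 218 ± 71.8 units against 0.920 ± 1.59 (7.09 ± 1.06, adjusted p = 2.2e-07), RTKN (6.16), the peroxisomal-family transporter gene ABCD4 (5.92), MCRIP1 (5.82) and the snoRNA host SNHG25 (5.80). PTPRCAP, SCRN2 and RELL2, which overlap CORO1B, LRRC46 and FCHSD1, had 0 cytoplasmic reads. MYC was not called (-0.04). AP3S1 overlaps ATG12. Of 68 ribosomal protein genes 35 were cytoplasmic and 2 nuclear (38 and 2 adjusted over the list alone), with camera at 7.9e-19 and adjusted p = 0.958 with an estimated correlation. Of 41 secretory genes 12 were nuclear and 1 cytoplasmic (14 and 1 adjusted over the list alone), led by LAMP1 (4.58) and AZGP1 (3.85). Their camera adjusted p was 0.0173, with adjusted p = 0.958 with an estimated correlation. Cholesterol genes had 6 of 20 nuclear (7 adjusted over the list alone), including SREBF1 (3.36), and heat shock genes 5 of 15 cytoplasmic (7 adjusted over the list alone), including HSPB1 (-3.55).

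DMSO had 1500 genes higher in the nucleus and 603 in the cytoplasm (3454 at an unadjusted p under 0.05), and 2696 and 2955 after rescaling, which moved the median from 0.63 to 0.14. Which side held more genes rests on the scale: edgeR gave 992 and 995 on the ERCC scale and 3728 and 2356 with TMM. The count of 2103 was 876 without DMSO nuclear replicate 1, 1198 without DMSO nuclear replicate 2 and 1356 without DMSO nuclear replicate 3. Without DMSO cytoplasmic replicate 2, 884 were nuclear and 1863 cytoplasmic, and the call of SNHG25 was lost. With only the DMSO nuclear and cytoplasmic libraries in the fit 652 genes were called, and the calls of ACTB and GAPDH were lost. Under JQ1-VHL 307 genes were higher in the nucleus and 2938 in the cytoplasm (4163 at an unadjusted p under 0.05), and 3257 and 3205 after rescaling, where leaving out any 1 of the 6 libraries gave more cytoplasmic than nuclear genes. The naming rule did not cover that comparison, apart from fixed genes such as ACTB (-4.11 ± 0.74, adjusted p = 1.3e-06).

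Genes with more exons and longer genes kept more of their new RNA than the typical gene. In rescaled nuclear RNA the genes with fewest exon blocks (median 5) changed by -0.14 ± 0.16 and those with most (median 25) by 0.58 ± 0.25 (SD of 3 pairs, the lowest and highest 25% of genes). By length, the shortest genes (median 9.01 kb) changed by -0.19 ± 0.12 and the longest (median 138 kb) by 0.50 ± 0.23. Across 10072 genes, which are not independent replicates, Spearman correlations with the number of exon blocks were 0.259, 0.237 and 0.284 in total, nuclear and cytoplasmic RNA, and with length 0.185, 0.220 and 0.131. A read counted in several intervals adds to a gene's sum each time, so these correlations also carry the number of intervals per read. Correlations with GC content were -0.03, -0.08 and 0.02.

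Intervals of a few kb had lower log2 changes than short ones in all 3 fractions. After rescaling, intervals up to 150 bp changed by 0.24 ± 0.13 and those of 3001 to 10000 bp by -0.17 ± 0.11 in nuclear RNA, by 0.11 ± 0.11 and -0.30 ± 0.02 in total RNA, and by 0.29 ± 0.12 and -0.03 ± 0.09 in cytoplasmic RNA. The longest nuclear intervals, over 10000 bp, changed by 0.05 ± 0.16, so the change did not grow with length throughout. On the ERCC scale these were -1.31, -1.72 and, over 10000 bp, -1.50 in nuclear RNA, -0.09 and -0.49 in total RNA, and 0.25 and -0.07 in cytoplasmic RNA. Within 1825 genes the longest interval (median 7162 bp) changed relative to the shortest (148 bp) by -0.26 ± 0.25 in nuclear RNA, where pair 2 gave 0.02, by -0.12 ± 0.03 in total RNA and by -0.04 ± 0.04 in cytoplasmic RNA. Of these genes 61.4% had the lower value at the longest interval in nuclear RNA. Long intervals were more nuclear than short ones under both treatments: the nuclear over cytoplasmic ratio after rescaling went from -0.33 ± 0.14 up to 150 bp to 0.98 ± 0.21 over 10000 bp in DMSO, and from -0.27 ± 0.08 to 1.35 ± 0.09 under JQ1-VHL. On the ERCC scale the same ratios were -0.51 ± 1.56 and 0.80 ± 1.52 in DMSO, and -1.96 ± 0.33 and -0.34 ± 0.37 under JQ1-VHL, so long intervals were not nuclear there under JQ1-VHL.

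**Figure D4:**
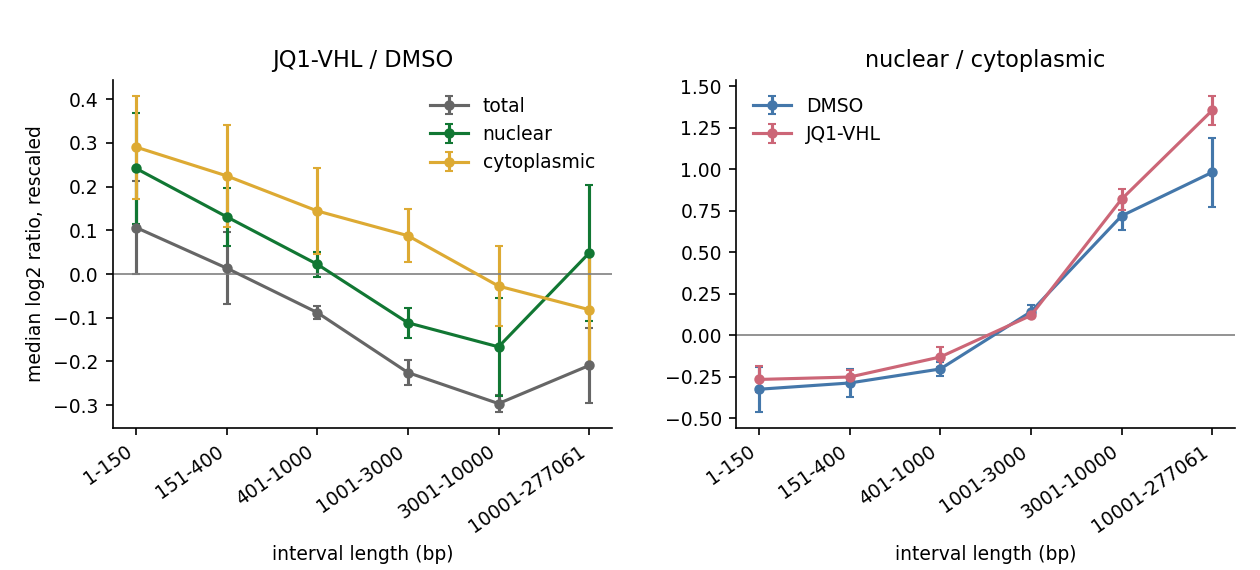
Median rescaled log2 ratio by interval length in 6 classes (bp); left, JQ1-VHL over DMSO in total, nuclear and cytoplasmic RNA, and right, nuclear over cytoplasmic RNA under DMSO and JQ1-VHL; points are means of 3 same-numbered pairs and bars their SD. Nuclear intervals go from 0.24 up to 150 bp to -0.17 at 3001 to 10000 bp and 0.05 over 10000 bp, while on the ERCC scale all are lower under JQ1-VHL (-1.31, -1.72 and -1.50); intervals over 10000 bp stand at 1.35 nuclear over cytoplasmic under JQ1-VHL, and at -0.34 on the ERCC scale.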

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

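The tests on the spread of the library sums and the test without the pair of libraries that stand apart were chosen only after the results were seen. The effect of JQ1-VHL differed between nucleus and cytoplasm for 3 results. Immediate early and short-lived mRNAs had an adjusted p of 8.97e-05 by camera in the nuclear minus cytoplasmic effect, and histone genes also had 8.97e-05, both higher in the nucleus relative to other genes. Both missed the threshold with an estimated correlation (adjusted p = 0.997). After rescaling 298 genes differed between the compartments.

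Chance was not excluded as the source of the 298 genes. Of 100 drawn splits of the libraries, the real one included, 8 gave as many genes after rescaling, and the highest other gave 2296. The split of that count kept the nuclear labels whole and exchanged cytoplasmic ones. It therefore still held the nuclear drug effect, for which limma called 2999 genes after rescaling. Splits of this kind are no reference without a drug effect, so the 8 of 100 cannot decide whether chance gave the 298 genes.

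The other comparisons have 10 splits each, too few for a share under 0.05. The real split had the highest count in 9 of the 10 tests, so 1 split gave as many: 309 genes in total RNA against 0 in any other split, and 3413 against 0 after rescaling. Nuclear RNA had 3453 against 0, and 2999 against 0 after rescaling. Rescaled cytoplasmic RNA had 3972 against 76. DMSO nuclear against cytoplasmic RNA had 2103 against 2096, and 5651 against 0 after rescaling, and JQ1-VHL nuclear against cytoplasmic RNA had 3245 against 3, and 6462 against 2. In cytoplasmic RNA on the ERCC scale 3 splits gave at least the 397 genes of the real one. The highest, 1006, set DMSO replicates 1 and 3 with JQ1-VHL replicate 2 against the rest, and it parts all 3 pairs as the real split does. With the batch number as a block the real split gave 619. Among the 4 splits that part all pairs, the highest other counts were 68 in rescaled cytoplasmic RNA, 4 in DMSO nuclear against cytoplasmic RNA and 0 in the other tests, apart from that 1006.

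The wide spread of the library sums between replicates was weighed first. If 1 factor per library made it, removing each library's median would remove most of the spread within groups. The share left was 0.499 ± 0.266 (mean and SD of 6 groups), so the mean leaves that open. An earlier wording of the bound would have read the same value as in favour. The share was 0.23, 0.34 and 0.31 in DMSO total, nuclear and cytoplasmic RNA, and 0.46 in JQ1-VHL nuclear RNA. It was 0.89 and 0.76 in JQ1-VHL total and cytoplasmic RNA, where the sums spread least. Where the sums spread more widely, most of the spread therefore went with the library medians. Whether an error of the ERCC scale gave this shared part stays open. A few abundant genes were argued against, since the DMSO cytoplasmic sums spread 10.3-fold without the 50 highest genes and 10.4-fold with them. Labelling that differed between whole cultures predicts total sums within the range of the nuclear and cytoplasmic sums of the same number: 2 of 6 lay outside and 0 by more than 1.5 times, which leaves it open. A real difference in transcription between cultures is a further candidate explanation that was not tested.

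Ribosomal protein mRNAs stood higher in the nucleus relative to other genes by 1.04 ± 0.20 (68 genes, SD of 3 pairs). If reads of mRNA made before the label were counted as T-to-C, the difference should shrink in intervals rich in nuclear reads. It was 1.24 ± 0.33 in 21 such intervals and 0.49 ± 0.19 in 199 other intervals of these genes, so it did not shrink. To argue against the explanation, the value less its SD had to reach the gene-level 1.04. It fell short of that bound, and the intervals were few, so the explanation stays open. The number of exon blocks and gene length were argued against, since the difference from 1004 matched genes was 1.48 ± 0.31. A slower loss or retention of these mRNAs in the nucleus may contribute and remains untested.

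The effect on immediate early mRNAs, relative to other genes, stood higher in the nucleus than in the cytoplasm by 0.95 (SD of pairs 0.43). The pair of libraries that stand apart, DMSO cytoplasmic replicate 3 and JQ1-VHL nuclear replicate 3, was argued against, since the difference was 1.61 without them. JQ1-VHL cytoplasmic replicate 3 also stood apart in its group and was kept, so its part was not tested. Against 393 genes matched on exon blocks and length the difference was 0.68 ± 0.44, compared with 0.97 unmatched, so gene structure stays open. A biological difference, such as short-lived mRNAs that leave the cytoplasm faster than the nucleus, could give the same pattern and was not tested.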

How the results depend on the processing

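The tests per interval, with the highest interval per gene, without the pair of libraries that stand apart, and with rescaling combined with leaving out a library were chosen only after the results were seen; the other alternatives were planned. Of the contrast counts under alternatives, 103 stayed within 1.5 times the reported count with the same balance of directions, 65 moved further and 24 changed their balance of directions. Of the values of gene lists, 456 kept direction and side of the threshold, 21 lost a call and 23 gained one. Of the values of named genes, 2966 kept both, 159 lost a call, 151 gained one and 33 reversed. Sign changes with neither value past the threshold counted as kept: 151 for named genes, 26 for lists and 8 of the 42 values of sums and medians, which all moved by less than the spread between pairs. For each changed value below the cause was not tested, except where a higher filter tested fewer genes or a smaller fit held fewer libraries. The planned scaling to Drosophila lines and the sum without mitochondrially encoded genes were not run, since the table holds neither.

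Rescaling gave 3413 genes in total RNA, 2999 in nuclear RNA, 3972 in cytoplasmic RNA, 298 in the nuclear minus cytoplasmic effect, 5651 in nuclear against cytoplasmic RNA in DMSO and 6462 under JQ1-VHL. edgeR with TMM gave 3809, 3130, 2987, 345, 6084 and 6427 for the same comparisons. Rescaling changed which direction held more genes in each of these except the nuclear minus cytoplasmic effect, and TMM did so in total RNA, cytoplasmic RNA and JQ1-VHL nuclear against cytoplasmic RNA. Against the rescaled balance, TMM changed it in nuclear RNA and in DMSO nuclear against cytoplasmic RNA. edgeR on the ERCC scale gave 229 in cytoplasmic RNA and 1987 in DMSO nuclear against cytoplasmic RNA, and DESeq2 gave 914 in total RNA and 24 in the nuclear minus cytoplasmic effect. A pseudocount of 0.1 gave 61 in total RNA, and a pseudocount of 10 gave 511 in total and 169 in cytoplasmic RNA. Without a filter total RNA had 630, and with a mean of 50 or more there were 42 in total RNA, 143 in cytoplasmic RNA and 1266 in DMSO nuclear against cytoplasmic RNA. A fit of the compared groups alone gave 580 in total, 5365 in nuclear and 0 in cytoplasmic RNA, and 652 in DMSO nuclear against cytoplasmic RNA. eBayes without trend or robust gave 528 in total RNA and 6 in the nuclear minus cytoplasmic effect.

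The batch number as a block gave 583 in total RNA, 619 in cytoplasmic RNA and 8 in the nuclear minus cytoplasmic effect. The block fits 1 shift per batch number, shared by all 6 groups, and is not a paired test within a fraction. The other counts stayed within 1.5 times with the block, and no named call was lost with it. The block and rescaling together gave the same changes for the named genes as rescaling alone.

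DMSO cytoplasmic replicate 3 and JQ1-VHL nuclear replicate 3 were left out together as libraries that stand apart. The counts without them were 693 in total, 567 in nuclear and 137 in cytoplasmic RNA, and 901 in the rescaled nuclear minus cytoplasmic effect. JQ1-VHL cytoplasmic replicate 3 also stood apart from replicates 1 and 2 of its group but was kept. Its chi-square per degree of freedom, on whole reads of 1 interval per gene, was 16.2 and 15.9 against them, and 2.67 between them. The highest interval per gene gave 2097 in nuclear RNA, 3 in the nuclear minus cytoplasmic effect and 3382 in DMSO nuclear against cytoplasmic RNA. Tests per interval have another denominator. They gave 2108 in total, 11001 in nuclear and 1382 in cytoplasmic RNA, 15 in the nuclear minus cytoplasmic effect, and 15178 and 22165 in nuclear against cytoplasmic RNA in DMSO and under JQ1-VHL. Per interval and rescaled they gave 11665, 10984, 10674, 232, 29099 and 30715.

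Leaving out 1 library at a time gave 18 to 236 genes in total RNA, 239 to 4150 in nuclear RNA, 74 to 1287 in cytoplasmic RNA, 0 to 106 in the nuclear minus cytoplasmic effect, and 876 to 2747 and 2406 to 3096 in nuclear against cytoplasmic RNA in DMSO and under JQ1-VHL. After rescaling the ranges were 1936 to 3178, 1892 to 2816, 3203 to 4261, 95 to 512, 4786 to 5451 and 5721 to 6450. A group left with 2 libraries took its spread from the pooled fit.

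In nuclear RNA 7 named genes reversed, with values under rescaling (and the same with the block), edgeR with TMM, and rescaling without both libraries that stand apart. These were 1.30, 1.12 and 0.80 for ERBB2, 1.51, 1.23 and 1.56 for NXF1, 1.11, 0.82 and 1.00 for SON, and 1.36, 1.07 and 1.34 for SRRM2. They were 1.75, 1.47 and 1.63 for ACTB, 1.64, 1.35 and 1.40 for GAPDH, and 0.97, 0.66 and 0.80 for MCL1. Under rescaling without both libraries only, BRD2 reached 0.27, BRD3 0.090 and ALYREF 0.33 in nuclear RNA, and BRD2 1.83 and SON 0.75 in the nuclear minus cytoplasmic effect. With a mean of 50 or more, the correlations with gene length and exon blocks in total RNA were 0.144 and 0.220, and that with GC content in nuclear RNA was -0.0873.

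The number of T-to-C reads limits genes with few of them. At least 10 reads were found in 6815 genes of JQ1-VHL cytoplasmic replicate 3 and in 7624 genes of JQ1-VHL nuclear replicate 3. In DMSO cytoplasmic replicate 3, 1 read was worth 2.75 units. On the ERCC scale limma called 0 of the planted changes of up to 2 on the log2 scale. After rescaling it called 92% of those at -2 in total RNA. The simulation planted few changed genes and no shift shared by all genes, so it does not set the limit for these data. In nuclear RNA limma called ALYREF at -2.06 (adjusted p = 0.048).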

Other observations

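The tests on the shares of the highest genes, the spread within groups and the resemblance of libraries were chosen only after the results were seen. The 50 genes of highest mean over all 18 libraries held a larger share of the summed value under JQ1-VHL in each fraction. The cytoplasmic libraries, with the largest sums, weigh most in that mean. The set is therefore not that of the most abundant genes of each fraction. These 50 genes held 13.4% to 15.5% of the summed value in the JQ1-VHL nuclear libraries, and 6.92% to 9.07% in the DMSO nuclear ones. The shares were 25.5% to 28.5% against 18.9% to 20.2% in total RNA, and 30.6% to 34.3% against 24.6% to 29.1% in cytoplasmic RNA. Some list members were called after rescaling in the nuclear minus cytoplasmic effect, a set for which chance was not excluded. NELFE, a subunit of the pausing factor NELF, differed by -3.23 (adjusted p = 0.044), like NELFCD, and the luminal factor gene SPDEF by -2.52 (adjusted p = 0.034). In the other direction stood the ribosomal protein mRNA RPS20 at 2.49 (adjusted p = 0.00045) and the nuclear pore gene NUP153 at 2.54 (adjusted p = 0.0027). The keratin gene KRT7, a marker of epithelium, differed by -2.65 (adjusted p = 0.022). These values are from limma after rescaling, with 3 libraries per group.

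Most of the spread between replicates was shared by all genes of a library in some groups and not in others. The median within-group SD of a gene went from 1.13 to 0.26 on the log2 scale after removal of library medians in DMSO total RNA, and from 1.66 to 0.52 in DMSO cytoplasmic RNA. It went only from 0.40 to 0.36 in JQ1-VHL total RNA and from 0.72 to 0.55 in JQ1-VHL cytoplasmic RNA.

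The replicate numbers did not always pair the libraries that resembled each other. After removal of library medians, the gene deviations of JQ1-VHL nuclear replicate 2 correlated at 0.21 with JQ1-VHL nuclear replicate 1, at 0.30 with DMSO nuclear replicate 1 and at 0.31 with JQ1-VHL total replicate 1. The correlations were -0.14 with DMSO nuclear replicate 2 and -0.10 with JQ1-VHL total replicate 2. Deviations of a group's 3 libraries are tied through their shared mean, so the 0.21 within a group is not comparable with the values between groups. No swap of labels was assumed, and the numbers of the labels were kept.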
